A study of Mus musculus and Rattus norvegicus with 2 samples.

How the data were processed

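Small RNAs were measured in sperm from the cauda epididymis, the tail of the duct in which sperm mature and are stored, of the mouse and the rat. There was 1 library per species. The mouse library came from C57BL/6 animals of 2 months and the rat library from Sprague Dawley animals of 450 g. Per the labels' protocols, total RNA was extracted with Trizol, the fraction of 18 to 45 nt was taken into Illumina libraries, and a GAIIx instrument was used. How many animals went into each library is not given in the sources used here.

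The deposited values are counts: for each distinct sequence, the authors gave its number of reads, the strand of the match, the database entry it was assigned to and the mismatches, with at most 2 mismatches, per the file headers. The entries came from miRBase, Rfam and GenBank, per the file headers. Per the submitters' processing notes, Bowtie 0.12.7 and the builds mm9 and rn5 were used, with no role given for either build. Adapter trimming, the order of the databases and the choice among several matches are not given in the sources used here. Each sequence has 1 assignment, so splitting or leaving out sequences with several annotations could not be tried.

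The mouse table holds 89179 sequences and 691381 reads, and that of the rat 137388 sequences and 2102735 reads. Of the mouse sequences, 2535, or 2.84%, have no count and an identifier turned into a month and year, as a spreadsheet program does to paired numbers. They were left out of the main values. Reading the month as the count gave 7 to 12 reads each and 22971 reads together, with 0 counts out of falling order, and this was tried as an alternative. A last mouse line with no sequence gives the total of 691381 reads and was left out of all sums.

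Identifiers rank the sequences by count, and some identifiers are not listed in the tables used here. If every identifier stands for 1 sequence, 78279 mouse and 63001 rat identifiers are not listed. Since counts fall with rank, they would hold at least 842375 mouse reads and at least 333168 rat reads, or 54.1% and 13.7% of listed, restored and unlisted reads together. The lowest listed identifier is 4 in the mouse and 1 in the rat. All shares below are of the listed reads, and the reads under the other identifiers were not analysed here.

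For matches on the minus strand the printed sequence is the reverse complement of the read, as the positions of the mismatched bases show, so those sequences were turned back before use. Sequences were grouped into 9 RNA classes by their deposited annotation. Families of tRNA 5′ ends were assigned by the first 18 nt, directly or after 1 extra base, with at most 1 mismatch, against 30 hand-written 5′ ends of 26 families. Those 5′ ends are textbook sequences and no tRNA reference was used. Mature miRNA names were matched between species after 16 rat names were replaced by their mouse forms. Counts were scaled to a sum of 1000000 miRNA reads (RPM), and log2 ratios of mouse over rat used a pseudocount of 1 RPM. For mouse reads, exact sense matches to GENCODE M21 transcripts (GRCm38) were counted. In both libraries, sequences of at least 100 reads were also aligned with edlib to the mouse mitochondrial transcripts, with edits of up to 15% of their length.

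With 1 library per species there was no replicate check and no test, no p-value was computed and no changed RNAs were counted. Species, strain, age or weight, and library cannot be separated. Shares carry exact Clopper-Pearson 95% intervals and single counts exact Poisson 95% intervals. These cover counting error only, since PCR copies of a read are not independent molecules. A count of 0 allows a share of up to 0.000434% in the mouse and 0.000143% in the rat, taking 3 counts as the limit, for sequences that the tables would list.

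The RNAs named were fixed before the data were examined: measured members of 8 miRNA lists, the 10 most abundant miRNAs of each library, the 5 largest log2 ratios each way among miRNAs with at least 100 reads in one library and 10 in the other, the 5 most abundant with at least 100 reads in one library and 0 in the other, a list of tRNA families, the 10 most abundant tRNA families, every rRNA parent and the 3 most abundant sequences of each main class. Part of these RNAs are named in the text and the rest enter only the counts, shares and medians. One sequence is not reported here. In the list counts and medians, members with at least 10 reads in either library were counted as measured. The median log2 ratio of each list was placed among 10000 random lists of the same size matched on mean expression, each member being drawn from the 15 miRNAs nearest in expression. That percentile describes these 2 libraries. The alternatives covered filters on counts and lengths, scaling, pseudocounts of 0.1 and 10, and the weight given to distinct sequences. Alternatives chosen after seeing the data were the scaling of the lists to all listed reads, the restored counts, perfect matches only, miRNAs and tRNA families by sequence under any label, and a reassignment of mRNA, unknown, piRNA and miRNA precursor reads. In that reassignment a read moved to tRNA, rRNA or mitochondrial RNA, in that order, if it shared an 18-mer that had at least 10 reads in the class over both libraries together. It was repeated with the reads of those classes thinned to equal totals in the 2 libraries.

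The log2 ratio, its interval and the list percentile were tested on counts simulated for the 286 miRNAs of the mouse and rat comparison. There were 50 runs per setting with a 4-fold change. Both simulated libraries had Poisson noise and were scaled by the same unchanged total. Recovery and coverage below therefore test neither the scaling to the miRNA total nor noise beyond counting error. In the first setting tried, 20 miRNAs changed and the list held 8 of them. The median recovered log2 ratio was 2.01 and 96.4% of 1000 intervals held the true value, but the percentile exceeded 97.5 for only 16 of 50 changed lists, and 3 of 50 unchanged lists fell outside 2.5 to 97.5. After that result a second setting was added in which the 8 list members were the only miRNAs that changed. There 50 of 50 changed lists exceeded 97.5, 1 of 50 unchanged lists fell outside, and 93% of 400 intervals held the true value. The method was the same in both settings, so the percentile misses most changed lists when many other miRNAs differ as well, and a percentile between 2.5 and 97.5 was not read as a lack of difference. Analyses used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and edlib 1.3.9.post1.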

Results

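Small RNAs of cauda epididymal sperm were counted in 1 mouse library and 1 rat library. The mouse table listed 691381 reads of 89179 distinct sequences and that of the rat 2102735 reads of 137388. Each comparison below sets the mouse beside the rat, with 1 library per species and therefore no replicate error. Intervals cover counting error at 95% only, and shares are of the listed reads.

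The main RNA classes were ordered differently in the 2 species. Fragments of tRNA, the adaptor of translation, held 53.8% of the mouse reads (interval 53.7 to 54.0) and 16.3% of the rat reads (16.3 to 16.4), a 3.30-fold higher share in the mouse. Fragments of rRNA, the RNA of the ribosome, held 19.04% of the mouse reads (18.9 to 19.1) and 51.4% of the rat reads (51.3 to 51.4), a 2.70-fold higher share in the rat. Reads annotated as mitochondrial RNA made up 6.50% in the mouse and 0.499% in the rat. Reads annotated as mature miRNAs, which guide silencing of mRNA, made up 3.40% in the mouse (3.36 to 3.44) and 1.23% in the rat (1.22 to 1.25). A separate class, annotated as miRNA precursor, held 1.06% and 1.71%. Of that class, 83.8% in the mouse and 61.6% in the rat were of 20 to 24 nt.

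**Figure D1:**
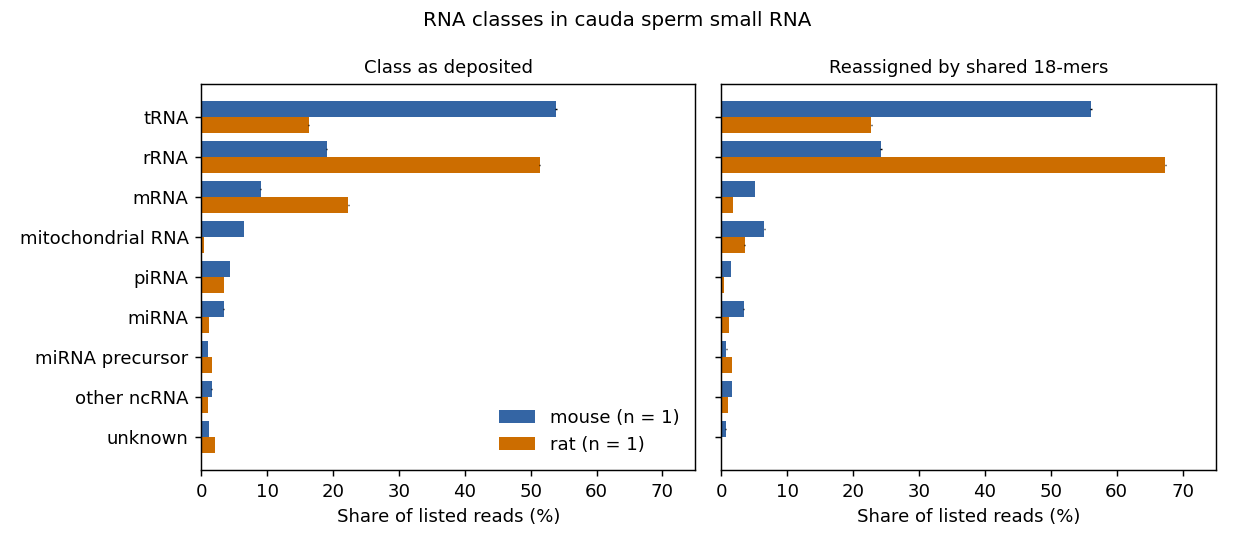
Share of listed reads (%) in each RNA class for the mouse and the rat library, as deposited on the left and after reassignment by shared 18-mers on the right, with 95% Clopper-Pearson intervals that are narrower than most bar edges. The rRNA bar of the rat stands at 51.4% on the left and 67.4% on the right, and the mRNA bars change order between the panels.

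Reads annotated as mRNA held 9.01% in the mouse and 22.3% in the rat, but this order did not hold by sequence. In the rat, 68.2% of the reads annotated as mRNA shared an 18-mer with rRNA reads, 13.7% with mitochondrial reads and 10.1% with tRNA reads, against 39.1%, 0.0321% and 4.04% in the mouse. After reassignment, mRNA held 5.12% in the mouse and 1.80% in the rat, tRNA 56.1% and 22.7%, rRNA 24.2% and 67.4%, and mitochondrial RNA 6.53% and 3.55%. The reassignment was chosen after seeing the data. With the reads behind the 18-mers thinned to equal totals in the 2 libraries, 67.8% of the rat and 39.05% of the mouse mRNA reads shared an 18-mer with rRNA reads. Among distinct sequences, rRNA accounted for 28.1% in the mouse and 44.0% in the rat, and tRNA for 5.67% and 4.66%. The reads not listed, at least 842375 in the mouse and 333168 in the rat, could not enter any of these shares.

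Both libraries peaked at 30 nt, which held 23.1% of the mouse and 13.3% of the rat reads. The window of 29 to 34 nt, typical of tRNA fragments, held 55.9% of the mouse reads and 43.6% of the rat reads, and that of 20 to 24 nt, typical of miRNAs, 12.7% and 23.0%. Fragments of tRNA in the mouse were nearly all long, with 96.4% at 28 to 36 nt. In the rat 64.8% were of that length and 26.2% were of 20 to 24 nt. Both libraries were counted here over reads annotated as tRNA, so tRNA fragments under other annotations are left out. Of the rat reads annotated as unknown, 91.7% shared an 18-mer with tRNA reads, and 93.5% were of 28 to 36 nt. Mature miRNAs had a modal length of 22 nt in both. Reads annotated as mitochondrial had a modal length of 43 nt in the mouse and 30 nt in the rat, where 50333 of 52285 reads of abundant sequences closest to mitochondrial RNA were annotated as mRNA instead. Without the 10 most abundant sequences of each library, the mouse excess at 29 to 34 nt, 12.3 percentage points, became -6.49 points, and counted over distinct sequences it was -11.9 points.

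**Figure D2:**
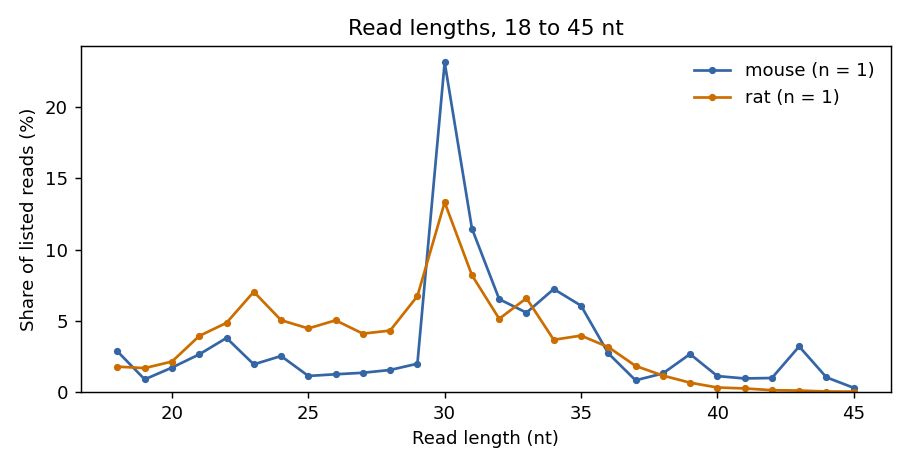
Share of listed reads (%) at each read length from 18 to 45 nt, 1 line per library. Both lines peak at 30 nt, at 23.1% in the mouse and 13.3% in the rat.

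Most tRNA fragments came from few families, and the family shares differed between the libraries. Reads outside the listed families held 3.12% of the mouse and 17.5% of the rat tRNA reads. The 5′ ends of tRNA-Gly led in both, with 156467 mouse reads (42.0% of the tRNA reads, 30 nt in the most abundant form) and 121385 rat reads (35.4%). Those of tRNA-Glu-CTC held 36.8% in the mouse, with 136945 reads, and 7.73% in the rat, with 26484 reads. Those of tRNA-Ala held 0.709% in the mouse and 17.6% in the rat, and those of tRNA-Ser-AGA/TGA 19 reads in the mouse and 20810 in the rat. The single sequence GCATTGGTGGTTCAGTGGTAGAATTCTCGC of tRNA-Gly was the most abundant listed RNA of both libraries, with 77639 mouse reads (Poisson interval 77094 to 78187) and 81435 rat reads (80877 to 81996). The mouse table starts at identifier 4, so 3 mouse sequences of at least as many reads would not be listed.

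Other families with a similar share in both were tRNA-Val, at 7.56% in the mouse and 6.21% in the rat, and tRNA-His, at 6.17% and 5.41%. The tRNA-Lys-CTT fragments held 2.14% and 0.456%, and tRNA-Cys 0.927% and 1.92%. The tRNA-Ala fragments were short in both libraries, with a modal length of 23 nt. Only 3.17% of them in the mouse and 0.0932% in the rat were of 28 to 36 nt, counted under any label. The rat tRNA-Ser-AGA/TGA fragments had a modal length of 24 nt. Within 28 to 36 nt, where few tRNA-Ala reads lay, the rat minus mouse difference of tRNA-Ala was 0.00309 points. That of tRNA-Gly turned to 11.1 points. Counted under any label, an alternative chosen after seeing the data, tRNA-His held 6.09% in the mouse (22982 reads) and 17.6% in the rat (78765 reads). Of these rat reads, 18557 were annotated as tRNA, and 20228 were the sequence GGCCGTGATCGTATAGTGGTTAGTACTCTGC, annotated as unknown. In the same count tRNA-Glu-TTC had 287 mouse and 21190 rat reads, and initiator tRNA-Met, which starts translation, 15 and 8354, while the shares of tRNA-Cys came to 1.55% and 1.54%. Of the tRNA families fixed beforehand, tRNA-Asp-GTC had 185 tRNA-annotated reads in the mouse and 47 in the rat, tRNA-SeC-TCA, which carries selenocysteine, 213 and 94, tRNA-Lys-TTT 868 and 303, tRNA-Leu-CAG/CAA 639 and 2369, tRNA-Gln 15 and 0, and tRNA-Ser-GCT 0 and 2829. Under any label the order of reads turned for tRNA-Gln, with 15 and 218, and for tRNA-SeC-TCA, with 213 and 402, and tRNA-Asp-GTC had 185 and 164. As a share of the tRNA-derived reads, tRNA-SeC-TCA went from 0.0572% and 0.0274% to 0.0564% and 0.0900%. The read numbers of these families are not corrected for the library totals of 691381 and 2102735 reads. Per listed read an order can therefore differ.

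**Figure D3:**
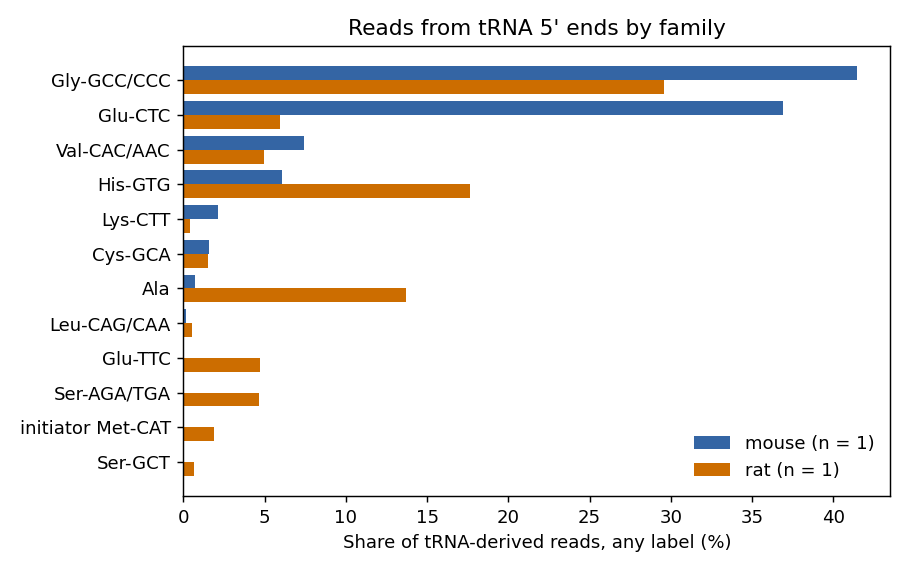
Share of tRNA-derived reads (%), counted under any label, for each tRNA family with at least 1000 reads in either library. The tRNA-Glu-CTC bar is 36.9% in the mouse and 5.93% in the rat, and the tRNA-Ala bar is 0.702% and 13.7%.

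Most reads annotated as rRNA had no named parent RNA. Parents were counted over these reads only, 131629 in the mouse and 1079776 in the rat. Reassignment by 18-mers raised the rRNA reads to 167581 and 1416588, and the parents of the added reads were not counted. The parent shares below therefore follow the deposited annotation, and their order between the libraries was not tested by sequence. Entries annotated only as GenBank rRNA held 55.0% of the mouse rRNA reads and 84.4% of the rat rRNA reads. The 18S rRNA of the small subunit held 26.5% (34869 reads) in the mouse and 6.62% (71486 reads) in the rat, the 5S rRNA 18.1% (23875 reads) and 7.80% (84272 reads), and the 5.8S rRNA 0.396% (521 reads) and 1.18% (12736 reads). Reads that began with CGCGACCTCAGATCAGAC, the 5′ end of 28S rRNA, numbered 97451 in the rat over 516 sequences under any label and 511 in the mouse over 2 sequences of at most 20 nt. Within 18 to 30 nt the rat minus mouse difference of 5S rRNA was -0.779 points, against -10.3 points over all lengths.

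Among mature miRNAs, miR-10a-5p, miR-16-5p, miR-191-5p, miR-22-3p and miR-143-3p were abundant in both species, and miR-34c-5p was abundant in the rat. miR-34c-5p, a miRNA of male germ cells and ciliated cells, had 255 reads in the mouse (10848 RPM, miRNA counts scaled to a sum of 1000000) and 5785 in the rat (222920 RPM), a log2 ratio of mouse over rat of -4.36 (interval -4.55 to -4.18). Its relatives miR-34b-5p, miR-34b-3p and miR-449a-5p had log2 ratios of -4.84, -2.91 and -2.37, and miR-34c-3p, with 20 and 37 reads, -0.74, which turned to 0.69 when scaled to all listed reads. On the other side, miR-143-3p, a miRNA of smooth muscle and stroma, had 2392 mouse and 813 rat reads (log2 ratio 1.70, interval 1.58 to 1.82). miR-99b-5p had 343 and 236 reads and miR-30a-5p 300 and 238. miR-191-5p had 2321 and 2920 reads, and its log2 ratio of -0.19 turned to 0.10 when scaled by the median ratio.

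**Figure D4:**
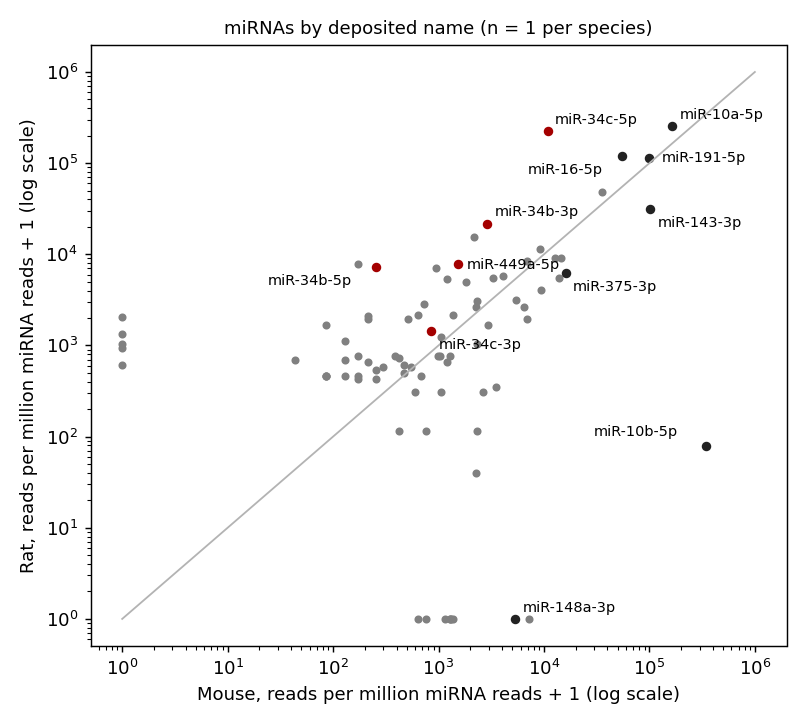
RPM of the miRNA reads plus 1 in the mouse (x) and the rat (y), both on log scales, for each miRNA name with at least 10 reads in either library. Equal values lie on the grey line, and the measured miR-34b, miR-34c and miR-449a members are in red. miR-34c-5p lies above the line at 10848 in the mouse and 222920 in the rat, and miR-10b-5p is plotted under its deposited name, which only 2 rat reads carry.

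Deposited names misplaced some miRNAs, and these were counted again by the first 18 nt under any label, after seeing the data. By name, miR-10b-5p had 8004 mouse reads and 2 rat reads, and miR-10a-5p 3856 and 6646. By sequence, TACCCTGTAGAACCGAATTTGT, the mature miR-10b-5p, was the most abundant rat sequence filed as miR-10a-5p. Reads with its first 18 nt numbered 8132 in the mouse and 3478 in the rat (log2 ratio 1.37), and those with the start of miR-10a-5p 3825 and 2832 (0.58). By name 2 miRNAs with at least 100 mouse reads had 0 rat reads, miR-6240 with 168 and miR-148a-3p with 125. By sequence miR-148a-3p had 149 mouse and 166 rat reads. Reads with the first 18 nt of the most abundant miR-6240 sequence numbered 85 in the mouse and 849 in the rat. That count misses part of the 168 named mouse reads, and the 849 rat reads carry other annotations. It therefore does not show a miRNA that is higher in the rat. miR-146b-5p had 22 mouse and 183 rat reads by name, and 222 mouse reads by sequence (log2 ratio 0.41).

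Among miRNAs with at least 100 reads in one library and 10 in the other, the other large log2 ratios by name were those of let-7f-5p (1.83), miR-375-3p (1.36), miR-127-3p (1.35) and miR-182-5p (1.29) toward the mouse and miR-21a-5p (-2.82) toward the rat. Across the 43 miRNAs with at least 10 reads in both libraries, log2 counts had a Pearson r of 0.82 and a Spearman rho of 0.79, over miRNAs that are not independent replicates, and their median log2 ratio was -0.29. Scaled to all listed reads instead, that median moved to 1.17, the log2 ratio of miR-34c-5p was -2.90, and those of miR-16-5p, miR-22-3p, let-7c-5p, miR-10a-5p, miR-191-5p and miR-34c-3p turned positive. In GRCm38, Mir34b lies on chromosome 9 at 51103562 to 51103645 and Mir34c at 51103034 to 51103110, both on the minus strand. Mir143 lies on chromosome 18 at 61649196 to 61649258 and Mir10b on chromosome 2 at 74726070 to 74726137.

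List members counted as measured had at least 10 reads in either library by deposited name. No fixed list with more than 1 measured member had a median outside the 2.5 to 97.5 percentile of matched random lists, which does not show that the lists were alike in the 2 libraries. Lists with 1 measured member cannot leave that range, since the member is drawn from 15 miRNAs. Of the 16 measured sperm and male germline miRNAs, 12 were higher in the rat and 4 in the mouse (median log2 ratio -0.68, percentile 12.7), but scaled to all listed reads 5 were higher in the rat and 11 in the mouse. Scaled to the miRNA total, the intervals of miR-100-5p, miR-25-3p and miR-34c-3p included 0. Of 8 let-7 members, 7 were higher in the mouse and 1 in the rat (median 1.31, percentile 95.3), and 8 were higher in the mouse when scaled to all listed reads. Scaled to the miRNA total, the intervals of let-7b-5p, let-7e-5p and let-7i-5p included 0. The lists follow deposited names: let-7g-5p had 30 and 0 reads by name but 33 and 21 by its first 18 nt (log2 ratio 0.79), and the start shared by let-7a-5p and let-7c-5p had 354 and 430 (-0.14), where let-7a-5p by name had a ratio of 0.80. The 5 measured members of miR-17-92 and its paralogues were all higher in the rat (median -0.73, percentile 47.7), against 1 of 5 scaled to all listed reads and 3 of 5 by the median ratio. The interval of miR-19b-3p (-2.99 to -1.02) excluded 0, while those of miR-25-3p, miR-92a-3p, miR-93-5p and miR-106b-3p included it. Of the X-linked testis cluster, 4 members were measured and 2 were higher each way (median 1.99, percentile 77.8), with miR-871-3p at 53 mouse reads and 1 rat read and miR-743b-3p at 3 and 29. The interval of miR-741-3p, with 3 and 12 reads, included 0. Other members of the cluster had reads but fewer than 10 in each library, and were not counted.

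Markers of other cells ranged from 0 reads to among the most abundant miRNAs, with miR-143-3p at rank 3 in the mouse and 6 in the rat and miR-375-3p at rank 7 and 17. Of the epithelial markers, miR-141-3p had 218 mouse and 104 rat reads and miR-200a-3p 3 and 18 (list median -0.61, percentile 45.7, and a median of 0.90 scaled to all listed reads). Of the 3 measured stroma and muscle markers, miR-143-3p was higher in the mouse, while miR-145a-5p had 13 and 15 reads and miR-199a-3p 7 and 15 (median -0.06, percentile 70.5), and scaled to all listed reads all 3 were higher in the mouse. Only miR-486-5p represented the blood cell markers at 10 reads or more, with 32 and 0 reads by name (percentile 96.7). Its reads were not counted again by sequence. Below that limit, miR-451a had 8 and 0 reads, miR-142-5p and miR-144-5p 1 and 1 each, and miR-150-5p 0 and 1. Only miR-375-3p represented the markers of other tissues, with 380 and 163 reads (percentile 90.04).

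Reads annotated as piRNA, the germline class that mostly starts with uridine, began with T in 70.2% of the mouse reads of 26 to 32 nt (interval 69.5 to 70.9) and in 13.4% of the rat reads (13.1 to 13.7). Among distinct sequences the shares were 82.9% and 63.4%. Of all piRNA-annotated reads, 39.2% in the mouse and 66.4% in the rat shared an 18-mer with tRNA reads. Without reads that shared an 18-mer with tRNA, rRNA or mitochondrial reads, 88.3% of the mouse and 78.1% of the rat reads began with T. That removal lowered the reads beginning with T from 12666 to 4899 in the mouse and from 8531 to 4286 in the rat. The most abundant piRNA-annotated sequence in the mouse was TCCCCTGTGGTCTAGTGGTTAGGATTCGGC, with 2937 reads, which shared an 18-mer with tRNA reads. In the rat it was CGCGACCTCAGATCAGACGTGGCGACCCG, from the 28S 5′ end, with 11645 reads.

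The libraries shared 15557 distinct sequences exactly, which held 74.6% of the mouse and 48.4% of the rat reads. Across these sequences, which are not replicates, log10 counts had a Pearson r of 0.49 and a Spearman rho of 0.39. Compared over the first 18 nt, shared starts held 85.3% and 81.9% of the reads. The listed mouse reads were more concentrated, without the 3 first identifiers, which are not listed: the 10 most abundant listed sequences held 39.7% of them, against 13.3% in the rat, and the 100 most abundant 59.1% against 37.1%.

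Mouse mitochondrial fragments came chiefly from the large ribosomal RNA of the mitochondrion. Exact matches to mt-Rnr2, the 16S rRNA gene at 1094 to 2675 on the plus strand of the mitochondrial genome in GRCm38, numbered 36264 reads, 86.9% of all mitochondrial matches. Those to mt-Rnr1, the 12S rRNA gene at 70 to 1024, numbered 2697, and those to mt-Th, the tRNA-His gene at 11546 to 11612, 1557. Protein-coding mitochondrial genes had 81 reads. The most abundant mt-Rnr2 sequence, at 1094 to 1136 with 3250 reads, was annotated as rRNA. Of the mt-Rnr2 reads, 44.4% lay within 1834 to 1933 and 18.4% within 2314 to 2413. The mouse numbers above are exact matches, and rat reads were only compared with the mouse genes with edits allowed. In the rat, 31948 reads of sequences with at least 100 reads were closest to mt-Tq, the mitochondrial tRNA-Gln, and 18398 to mt-Rnr2. By the same count, 21512 mouse reads were closest to mt-Rnr2. All mitochondrial genes together held 4.65% of the mouse and 3.36% of the rat reads of such sequences. Of these rat reads closest to mitochondrial genes, 50333 of 52285 were annotated as mRNA.

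**Figure D5:**
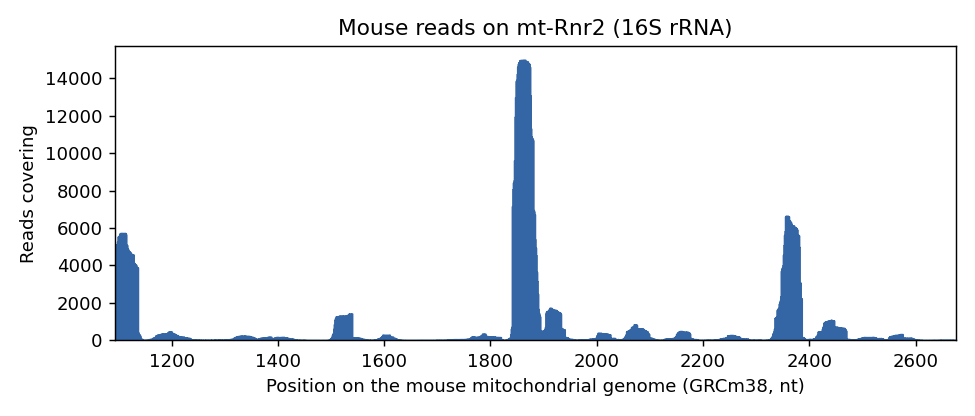
Number of mouse reads covering each position of mt-Rnr2 on the mitochondrial genome (GRCm38), from exact matches of 36264 reads. The highest peak lies within 1834 to 1933, which holds 44.4% of these reads.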

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

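The tests in this part were chosen only after the results were seen, except the 2 scalings used for miR-34b, miR-34c and miR-449a, which had been planned for single miRNAs. Reads outside the main counts existed in both libraries. The mouse sequences with a blank count held 22971 reads when the month in their identifier was read as the count, and 10.9% of these reads were annotated as tRNA. Identifiers not listed would hold at least 842375 mouse reads and at least 333168 rat reads, if every identifier stands for 1 sequence. These 3 amounts are given because the main counts leave them out, and they say only that such reads exist.

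The rRNA share was 32.3 points higher in the rat. Filing of rRNA under other annotations is argued against, since reassignment by 18-mers raised the difference to 43.1 points. Unlisted reads stay open: if all of them were rRNA, the mouse share would be 63.5%, above the 51.4% of the rat, and which RNAs they hold keeps this undecided. The mouse table lists the 28S 5′ end at no more than 20 nt, where the rat table lists it up to 55 nt. A difference between the species or in sperm handling was not tested.

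miR-34b, miR-34c and miR-449a were higher in the rat, by a median log2 ratio over 5 measured members of -2.91. All of these members except miR-449a-5p are arms of Mir34b or Mir34c, which lie close together on chromosome 9. miR-34a was not among the members, so the median does not describe the whole family. Wrong names are argued against by the count over the first 18 nt, which gave a median of -3.07. The median ratio scale gave -2.62. It moves all log2 ratios by about the same amount, set by their median of -0.29, so it is no separate test of scaling. Scaling to all listed reads gave -1.44 with miR-34c-3p reversed, so the size of the difference depends on the scaling. Unlisted sequences are argued against by single sequences listed in both tables, which gave a median of -2.32 relative to CAACGGAATCCCAAAAGCAGCTG of miR-191-5p. miR-34c-3p went the other way in that last test, at 0.82, on 15 and 13 reads. Strain, age, other cells in the preparation and the species itself cannot be separated with 1 library each and were not tested.

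The T-first share of piRNA-annotated reads was 56.8 points lower in the rat. A candidate explanation is that tRNA and rRNA fragments were filed as piRNA: without reads that share an 18-mer with those classes the gap was 10.2 points. What remains of the gap was not tested, and no biological explanation was tested.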

How the results depend on the processing

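Which alternatives were chosen only after the data were seen is given here by name: restored counts, reassignment by 18-mers (also at matched depth), any label, perfect matches, 18-mer filtering of piRNA reads, the first 18 nt of miRNAs and library scaling of the lists. In the class shares of reads, the differences of rat minus mouse in tRNA, rRNA, mRNA and mitochondrial RNA, in percentage points, kept their direction under every alternative run except for mRNA under reassignment. The reported differences were -37.5, 32.3, 13.3 and -6.00. With annotated reads only they were -37.8, 33.2, 13.7 and -6.07. With sequences of at least 10 reads they were -46.4, 35.5, 16.8 and -5.05. Without the most abundant sequence they were -35.1, 31.97, 13.1 and -6.80. Within 18 to 45 nt they were -38.1, 32.5, 13.4 and -5.80. Within 18 to 30 nt they were -31.8, 33.6, 9.24 and -2.66. With restored counts they were -36.2, 31.4, 13.2 and -6.20. After reassignment they were -33.4, 43.1, -3.32 and -2.98. After reassignment at matched depth they were -33.4, 43.1, -3.28 and -2.96. Over distinct sequences, the differences of tRNA and rRNA were -1.01 and 15.9, with at least 2 reads -2.57 and 14.5, and with at least 10 reads -7.68 and 17.8. The mouse minus rat difference at 29 to 34 nt of 12.3 points reversed to -6.49 without the 10 most abundant sequences and to -11.9 over distinct sequences, and was 11.2 with restored counts. The rat minus mouse differences of tRNA-Gly, tRNA-Glu-CTC, tRNA-Ala and tRNA-His were -6.62, -29.1, 16.9 and -0.76 points, with sequences of at least 10 reads -6.04, -29.7, 17.3 and -0.525, within 28 to 36 nt 11.1, -26.3, 0.00309 and 1.56, and under any label -11.9, -31.0, 13.0 and 11.5. Those of 5S and 18S rRNA, over reads annotated as rRNA, were -10.3 and -19.9. With sequences of at least 10 reads they were -14.6 and -15.8, and within 18 to 30 nt -0.779 and -17.8. The rRNA parents were not counted under any label. The log2 ratio of miR-34c-5p stayed negative under all alternatives run: -2.90 per listed read, -4.08 by the median ratio, -4.59 for the most abundant sequence, -4.60 with perfect matches and -4.14 over the first 18 nt. Per listed read, the ratios of miR-10a-5p, miR-191-5p, miR-16-5p, miR-22-3p, let-7c-5p and miR-34c-3p reversed to 0.82, 1.27, 0.33, 1.04, 1.16 and 0.69. Over the first 18 nt, among the miRNAs named above, those of miR-10a-5p, miR-191-5p, miR-146b-5p, miR-6240, miR-148a-3p and let-7a-5p reversed. They came to 0.58, 0.021, 0.41, -3.18, -0.013 and -0.14. The miR-6240 count misses part of its named mouse reads, and let-7a-5p shares its start with let-7c-5p. For the most abundant sequence miR-10a-5p gave 0.12 and miR-34c-3p 0.18, with perfect matches miR-10a-5p gave 0.27, and by the median ratio miR-191-5p gave 0.10. The T-first share of piRNA-annotated reads was, in the mouse and the rat, 68.7% and 14.0% at 24 to 32 nt, 73.2% and 16.3% at 29 to 31 nt, 82.9% and 63.4% over distinct sequences, and 88.3% and 78.1% without shared 18-mers. Shared sequences held 66.0% and 36.2% with at least 10 reads in each, and 85.3% and 81.9% over the first 18 nt. The top 10 starts of 18 nt held 54.9% and 25.6%. Where a value moved or reversed, the cause was not tested. Percentiles of lists with more than 1 measured member stayed within 2.5 to 97.5 under each alternative run, those with 1 cannot leave that range, and an alternative that left a list with 0 members has no value. In simulation the percentile exceeded 97.5 for only 16 of 50 changed lists when 20 miRNAs changed, so these percentiles cannot exclude differences. Splitting sequences with several annotations was not run, since each has 1. Depth and deposited names both limit single miRNAs: 43 names had at least 10 reads in both libraries. miR-10b-5p was not among them, with 2 rat reads by name and 3478 by its first 18 nt. The parts of depth and naming were not separated. No paired analysis was possible because each species has 1 library.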

Other observations

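The gene sets and RNAs in this part were chosen after their values were seen. Mouse reads annotated as mRNA included fragments of transcripts made late in sperm formation. Reads that matched 1 protein-coding gene exactly numbered 17972, 28.9% of the reads annotated as mRNA, and touched 5948 genes. Prm2, which packs sperm DNA, had 118 reads (interval 97.7 to 141.3), and Odf1 and Smcp, parts of the sperm tail and its mitochondria, had 102 and 88. Prm2 lies on chromosome 16 at 10791380 to 10796134 on the minus strand of GRCm38. Spem2 had 130 reads, Ybx2 65, Oaz3 46, Odf2 24, Prm1 18, Tnp2 15, Gapdhs 15, Spem1 5, Tnp1 3, Ldhc 3 and Akap4 2. A single sequence held 30 of the Spem2 reads and 14 of the Ybx2 reads, against 3 for Prm2, 3 for Odf1 and 4 for Smcp. The Spem2 and Ybx2 counts therefore rest more on copies of 1 sequence. Whether reads of these genes share 18-mers with rRNA reads was not tested.

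Genes listed for the epididymal epithelium also had reads, with 110 of Gpx3, 69 of Clu, 48 of Gpx5, 30 of Adam7, 24 of Crisp1, 10 of Lcn5, 5 of Rnase10, 3 of Defb20, 3 of Cst8 and 1 of Spink2. Whether these reads came from that epithelium was not tested. Of stroma and muscle genes, Col1a2 had 36 reads, Col1a1 30, Col3a1 24, Myh11 10, Acta2 5 and Vim 2. Of blood and immune genes, Cd52, which the epididymis also makes, had 29 reads, Cd74 4 and Lyz2 2, and Ptprc and S100a8 had 0. The globin genes Hba-a1 and Hbb-bs, which have near-identical copies, had 0 reads that matched them alone, and 7 and 2 when reads under any label that other genes share were counted. The genes with most reads, Lars2 with 443 and Tmem38b with 428, had 182 and 107 of them in a single sequence. No rat transcripts were used here.

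Fragments of tRNA-His carried an extra base before the first base of the tRNA body in 85.0% of the mouse reads (19531 of 22982, interval 84.5 to 85.4) and in 74.8% of the rat reads (58920 of 78765, interval 74.5 to 75.1). The extra base was G in 86.1% of these mouse reads, T in 9.34% and A in 4.48%, and G in 99.2% of the rat reads. Among the other families with at least 1000 reads, the highest share with an extra base was 0.113%, for tRNA-Ala in the mouse. Mature tRNA-His is known to carry an added G at that position. If the database entries end at the tRNA boundary, matching to them limits the comparison with other families, which was not tested.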
